A study of Mus musculus with 4 samples.

How the data were processed

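Serum of C57BL/6 mice was measured on antibody arrays, in which capture antibodies spotted on a support bind proteins of the sample and a biotin label makes the bound protein visible. The labels describe 4 samples: 2 sera of control mice, which the series calls vehicle controls, and 2 sera of mice with experimental autoimmune encephalomyelitis (EAE). Each array gave values for 32 proteins and 4 rows of control spots. The labels' protocol combines serum into a single tube and does not say how many mice stand behind a sample, so p-values measure only the spread between these samples, which may be technical. The day of sampling, the way EAE was induced, the imaging instrument and the spot-finding software are not given in the sources used here.

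The deposited per-sample values are intensities, the brightness of a spot, with replicate spots averaged before deposit: per the file headers and row names the positive, blank and negative spots are averages, and a further single blank spot is listed. The intensity values had neither been background-subtracted nor scaled between arrays, since blank spots averaged 9749 to 9982 and the positive controls 50210 to 54202. The authors also deposited a table of 32 protein ratios per array. Recomputing it showed that each ratio is the intensity minus the blank average, divided by the positive-control average minus the blank average, with a largest absolute deviation of 1.2e-07. In that table the blank is 0 and the positive control is 1. It is called the normalised signal here.

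The scale of the main test was fixed before the data were examined: log2 intensity divided by the array's positive-control average, without background subtraction, called brightness here. Brightness keeps the background of the support and therefore understates how much a protein changed. The normalised signal had also been chosen before the data were examined as a second scale, and is given as well, because it moved the median difference by over 1.5 times. All 4 samples entered 1 linear model with the group as the only term (limma 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over the 32 proteins with a threshold of 0.05. The model has 2 residual degrees of freedom, to which the pooling across proteins added 1.99 on the brightness scale and 4.09 on the normalised-signal scale. An exact permutation of 2 against 2 samples has 6 arrangements, so its smallest two-sided p is 0.333 and it cannot pass the threshold.

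Of 14 protein lists fixed before the data were examined, 12 had a measured member, and the 6 with at least 3 members were tested with limma's fry, adjusted over the 6 lists. Fry asks whether the members of a list move one way on balance and does not compare the list with other proteins. Camera, which makes that comparison, was run with a preset correlation of 0.01 and with an estimated one. Proteins were put on lists by name alone. The proteins named in the text were chosen by a rule fixed before the data were examined: all past the threshold, or the 20 with the largest differences if more passed; the 8 highest and 8 lowest differences among proteins whose groups did not overlap; 14 measured proteins fixed by name; and the extremes of each list. The rule named 31 proteins. CTACK was added after its values were seen, because it was 1 of 3 proteins that did not pass. Protein names are those of the files. A single mouse gene symbol was assigned by hand to 29 of the 32 proteins, and all 29 symbols are in the reference gene table of assembly GRCm38.p6; no genome coordinates are printed, since protein arrays carry no genome build.

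A protein was called not above background on an array where its intensity was at or below the brightest of the 3 background values (blank average, negative average and single blank). This definition was chosen after seeing the data. For proteins below it on both EAE arrays, folds are lower bounds: the control mean of log2 normalised signal against the EAE mean of, per array, the higher of the protein's own value and the lowest value among proteins above background. The number of arrays limits the precision. No spot-level replicates or pixel counts were used.

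The test was tried on simulated data: 100 panels of 32 proteins, of which 8 were lowered by 0.3 and 8 by 0.7 on the log2 scale. Means were those of the controls, and the spread was that after pooling across proteins. Noise was drawn independently for each protein and array. The test called 77.8% of the proteins lowered by 0.3, 99.8% of those lowered by 0.7 and 3.69% of the unchanged proteins. In panels without any change, 7% of the list tests had an unadjusted p under 0.05. The simulated arrays carried no shared shift, so these rates do not cover arrays that differ as a whole.

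Alternatives were the intensities without positive-control scaling, scaling of the arrays to the same median, quantile normalization, the authors' normalised signal, an offset of 0.1 of the median, normexp background correction on the 3 background values, 2 filters on dim proteins, limma with a trend or robust prior, a 1.5-fold rule without a test, leaving out each array, and the replicate number as a block. Alternatives without IL-4 and IL-10, without the 7 proteins below background on both EAE arrays, with crossed replicate numbers, and with both scalings after IL-4 and IL-10 were left out, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.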

Results

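Serum levels of 32 cytokines, chemokines, growth factors and related proteins were compared between mice with EAE, an autoimmune inflammation of the central nervous system used as a model of multiple sclerosis, and vehicle controls. Each group held 2 serum samples of male C57BL/6 mice, with 1 antibody array per sample. Median protein intensity was 20392 and 20734 on the control arrays and 12769 and 12000 on the EAE arrays. The 2 control arrays correlated with r = 0.90 across the proteins and the 2 EAE arrays with r = 0.97, where proteins are not independent replicates. The median absolute log2 difference in brightness between replicates was 0.12 for controls and 0.06 for EAE.

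Relative to the positive control of the array, every one of the 32 proteins had a lower mean in EAE serum than in control serum. On the brightness scale 29 proteins were lower past an adjusted p of 0.05 (limma) and 0 were higher. On the normalised signal of the authors, with the blank subtracted, 30 were lower and 0 higher. For 31 proteins both EAE values lay below both control values, an ordering that chance gives to a single protein in 16.7% of cases. The proteins were read on the same 4 arrays and are not independent, so a shared shift gives most of them this ordering at once. The median difference was -0.54 on the log2 brightness scale, or 1.45-fold lower, and -1.84 on the log2 normalised-signal scale, or 3.57-fold lower. The latter median is 2.88-fold when the 7 proteins not above background in EAE are set to their bounds. The median normalised signal of an array was 0.243 ± 0.0095 (SD, n = 2) in controls and 0.0608 ± 0.0073 (SD, n = 2) in EAE, and an exact two-sided permutation test gave p = 0.333, the smallest it can give. The count of 29 fell to 20 without EAE replicate 1 and to 19 without EAE replicate 2, where the median difference was -0.54 and -0.51. The spread then comes from the control arrays alone, and the remaining EAE sample is assumed to vary like them.

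**Figure D1:**
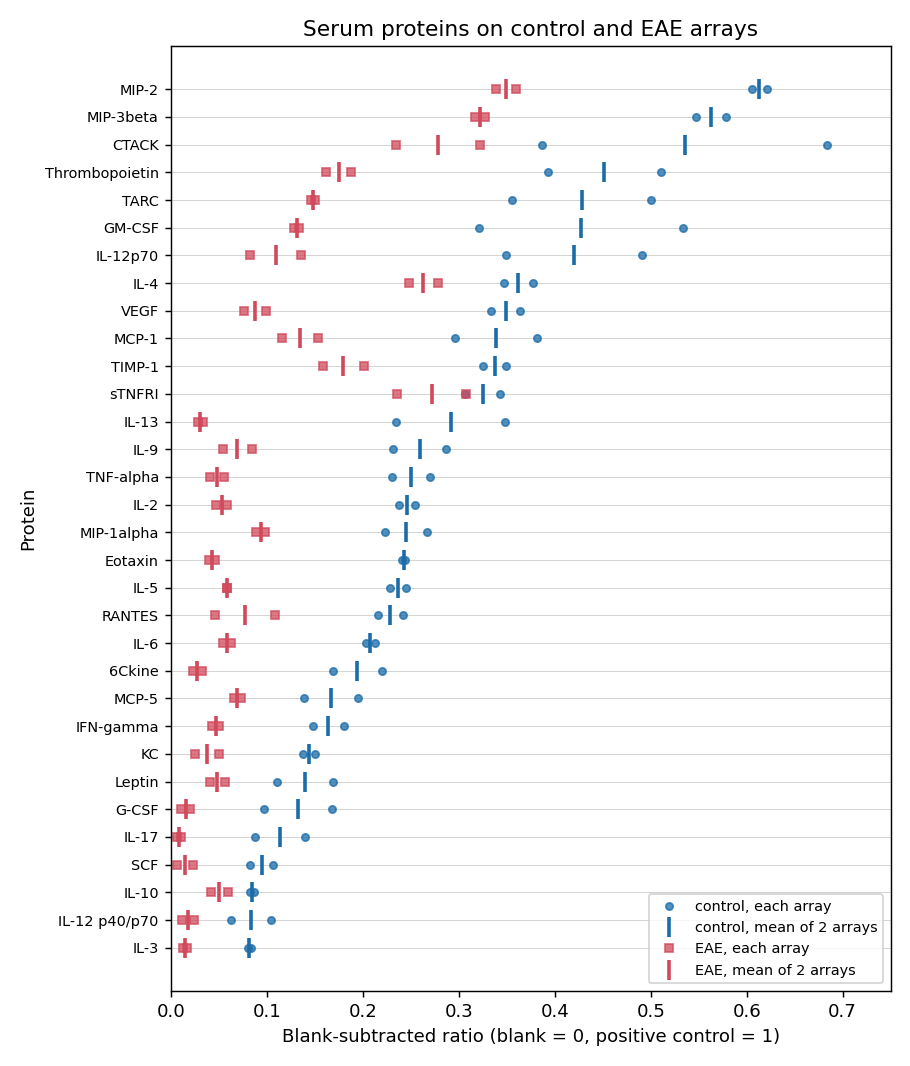
Normalised signal of each protein (x axis, no unit, blank = 0 and positive control = 1) on each of 2 control arrays (circles) and 2 EAE arrays (squares), with vertical ticks at the group means and proteins ordered by control mean. The EAE squares lie left of the control circles for 31 proteins; for sTNFRI the EAE values are 0.236 and 0.307 and the control values 0.343 and 0.306.

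The control spots did not show a fall of this size, but blank and negative spots, at the background level, cannot show whether less serum was applied. The positive control averaged 53743 ± 649 (SD, n = 2) on control arrays and 51232 ± 1445 (SD, n = 2) on EAE arrays, a difference of -4.67%, which the main scale divides out. The negative spots averaged 10529 ± 315 (SD, n = 2) and 10430 ± 148 (SD, n = 2), and the blank average 9924 ± 22.2 (SD, n = 2) and 9866 ± 164 (SD, n = 2). The median protein differed by -7413 intensity units between the groups. No protein lay at or below the brightest background value on a control array, whereas 7 did on EAE array 1 and 8 on EAE array 2. The 7 proteins below it on both EAE arrays were 6Ckine, G-CSF, IL-3, IL-12 p40/p70, IL-13, IL-17 and SCF, so their EAE levels are upper limits. On every array the brightest background value was the single blank spot, so this cutoff rests on a spot that was not averaged. It averaged 11042 ± 177 (SD, n = 2) on control arrays and 11221 ± 190 (SD, n = 2) on EAE arrays. 6Ckine and IL-13 lay above the negative average on both EAE arrays.

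All 6 measured members of the T helper 1 and 17 list were lower in EAE relative to the positive control, with a median of -0.59 in log2 brightness. With arrays scaled to the same median the list median became 0.07, and the median over all 32 proteins became 0.12. The T helper 1 and 17 lymphocyte classes drive the inflammation of EAE in the usual account of the model. IL-17, the signature cytokine of T helper 17 cells, had a normalised signal of 0.113 ± 0.037 (SD, n = 2) in controls and 0.0079 ± 0.0029 (SD, n = 2) in EAE, where it was not above background, and was at least 2.79-fold lower. IFN-gamma, the signature cytokine of T helper 1 cells, was 3.55-fold lower, at 0.163 ± 0.023 against 0.046 ± 0.0055 (SD, n = 2 each). TNF-alpha was 5.26-fold lower and IL-2, a T cell growth factor, 4.74-fold lower. IL-12p70, which promotes T helper 1 differentiation, was 3.92-fold lower, and the IL-12 p40/p70 antibody gave at least 2.03-fold. In brightness the log2 differences were -0.47 ± 0.10 for IL-17 (limma SE, adjusted p = 0.012), -0.47 ± 0.06 for IFN-gamma (adjusted p = 0.0047) and -0.75 ± 0.07 for TNF-alpha (adjusted p = 0.0028). The calls of IL-17 and IL-12 p40/p70 were lost when either EAE array was left out.

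Of the 5 T helper 2 and regulatory cytokines, 4 were lower in EAE past the threshold, with a list median of -0.66 in brightness that became 0.0075 under median scaling. IL-13 was not above background on either EAE array and was at least 7.22-fold lower in normalised signal (brightness adjusted p = 0.0047, limma). IL-5, a growth factor of eosinophils, was 4.07-fold lower and IL-9 was 3.85-fold lower. IL-4, the signature cytokine of T helper 2 cells, was 1.38-fold lower, with 0.362 ± 0.021 in controls and 0.263 ± 0.022 in EAE (SD, n = 2 each). Its brightness difference of -0.25 ± 0.06 passed (limma adjusted p = 0.022), whereas its normalised signal did not (adjusted p = 0.11) and the brightness call was lost without either EAE array. IL-10, an anti-inflammatory cytokine, had normalised signals of 0.0843 ± 0.0031 and 0.050 ± 0.013 (SD, n = 2 each). Its brightness difference of -0.12 ± 0.06 did not pass (limma adjusted p = 0.10), and its normalised signal did, at 1.71-fold lower (adjusted p = 0.035). The IL-4 and IL-10 intensities of both EAE arrays are the only protein values that are not multiples of 0.5.

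All 5 members of the innate proinflammatory list, IL-6, TNF-alpha, GM-CSF, IL-12p70 and IL-12 p40/p70, were lower, with a list median of -0.75 in brightness that became -0.08 under median scaling. IL-6, a driver of the acute-phase response, was 3.60-fold lower in normalised signal, at 0.208 ± 0.0064 against 0.0578 ± 0.0063 (SD, n = 2 each; brightness adjusted p = 0.0028, limma). GM-CSF, which activates myeloid cells, was 3.16-fold lower, and its control values of 0.321 and 0.533 were further apart than its EAE values of 0.133 and 0.128. Its brightness call was lost without either EAE array.

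Among 9 CC chemokines, 8 were lower in EAE in brightness and all 9 in normalised signal, with a median of -0.55 in brightness that became 0.11 under median scaling. Eotaxin, which attracts eosinophils, was 5.71-fold lower (brightness adjusted p = 0.0024, limma). Its EAE intensities of 11651.5 and 11595.5 lay close above the brightest background values of 11355 and 11087. The fold therefore depends on the background subtracted, and brightness gave 1.68-fold. Other proteins close to background, such as TNF-alpha and IL-10, share this limit. The lymph node chemokines 6Ckine and MIP-3beta share the receptor CCR7. 6Ckine was at least 4.86-fold lower, whereas MIP-3beta was 1.75-fold lower, from 0.563 ± 0.023 to 0.321 ± 0.0075 (SD, n = 2 each). This contrast depends on the scale. Their log2 differences in brightness were -0.67 and -0.51, and in intensity units scaled to the positive control MIP-3beta fell more (-10044 against -6734). The monocyte attractants MCP-1 and MCP-5 were 2.54-fold and 2.39-fold lower, MIP-1alpha 2.62-fold, RANTES 3.24-fold and TARC 2.86-fold. CTACK, a skin-associated chemokine, had control values of 0.387 and 0.684 and EAE values of 0.322 and 0.235. Its brightness difference of -0.55 ± 0.23 did not pass (limma adjusted p = 0.076) and became 0.11 under median scaling, and its normalised signal passed narrowly (adjusted p = 0.047). The 2 measured CXC chemokines, both neutrophil attractants, were lower as well, with a median of -0.49 in brightness that became 0.18 under median scaling. MIP-2 was 1.76-fold lower. KC was above background on 1 of the 2 EAE arrays and was 4.11-fold lower, or 3.25-fold with the other EAE array set to the lowest value above background.

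All 6 growth factors of blood cells were lower, with a median of -0.58 in brightness that became 0.08 under median scaling. Thrombopoietin, the regulator of platelet production, was 2.57-fold lower, at 0.452 ± 0.084 against 0.174 ± 0.018 (SD, n = 2 each). G-CSF, which drives neutrophil production, was at least 3.21-fold lower, SCF, the ligand of the KIT receptor, at least 2.35-fold and IL-3 at least 2.05-fold. The calls of G-CSF, SCF, IL-3 and GM-CSF were lost without either EAE array. The 3 measured proteins that platelets release during clotting were also lower, with a median of -0.55 in brightness that became 0.12 under median scaling. VEGF, an angiogenic factor, was 4.03-fold lower (brightness adjusted p = 0.0024, limma), and TIMP-1, an inhibitor of matrix metalloproteinases, was 1.89-fold lower (brightness adjusted p = 0.0066), with RANTES as given above. The TIMP-1 call was lost without EAE replicate 2. Leptin, the hormone of fat tissue, was 2.90-fold lower, and its brightness call was lost without either EAE array, as was that of MCP-5.

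The soluble receptor sTNFRI was the protein closest to its control level in normalised signal. It averaged 0.324 ± 0.027 in controls and 0.271 ± 0.051 in EAE (SD, n = 2 each), and its groups overlapped. The log2 difference was -0.13 ± 0.10 in brightness (limma SE, adjusted p = 0.25) and -0.27 ± 0.26 in normalised signal (adjusted p = 0.35).

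Each of the 6 tested lists was lower in EAE on balance relative to the positive control, a direction that median scaling turned for 5 of them and quantile normalization for 3 in brightness. Median scaling removed a shift of -0.66, larger than the median protein difference of -0.54, so the median over all 32 proteins itself became 0.12. Each list median under median scaling lay below that value, so these turns do not place a list above the typical protein. In normalised signal relative to its median 4 lists turned, with medians from 0.037 to 0.62, where the median over all proteins was 0.17. The T helper 1 and 17 and growth factor lists stayed below 0 at -0.28 each, with 2 of 6 and 3 of 6 members not above background in EAE. Fry gave adjusted p-values of 0.0063 for the T helper 1 and 17, innate and CC chemokine lists, 0.010 for growth factors, 0.014 for T helper 2 and regulatory cytokines and 0.015 for platelet-released proteins. No list passed a test against the rest of the panel, with adjusted p = 0.95 for each by camera with a preset correlation and adjusted p = 0.97 with an estimated correlation. In normalised signal, with members not above background at their bounds, the list medians were 3.73-fold, 3.85-fold, 3.60-fold, 2.62-fold, 2.85-fold and 3.24-fold lower for T helper 1 and 17, T helper 2 and regulatory, innate, CC, growth factor and platelet-released proteins. Fry on that scale, with values as measured, gave adjusted p-values of 0.011 to 0.032, and camera gave adjusted p = 0.56 to 0.73 with a preset correlation and adjusted p = 0.84 with an estimated correlation. Counts of lower members adjusted over the list alone equalled those over all 32 proteins: 6 of 6, 4 of 5, 5 of 5, 8 of 9, 6 of 6 and 3 of 3 in the order T helper 1 and 17, T helper 2 and regulatory, innate, CC, growth factors and platelet-released. These lists share members and are not separate results. TNF-alpha, IL-12p70 and IL-12 p40/p70 are on the T helper 1 and 17 and innate lists, and GM-CSF on the innate and growth factor lists. IL-5 is on the T helper 2 and growth factor lists, and RANTES on the CC and platelet lists. Without control replicate 1, 5 lists stayed below the threshold at adjusted p-values of 0.043 to 0.047, and without any other array the adjusted p-values were 0.051 to 0.117.

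**Figure D2:**
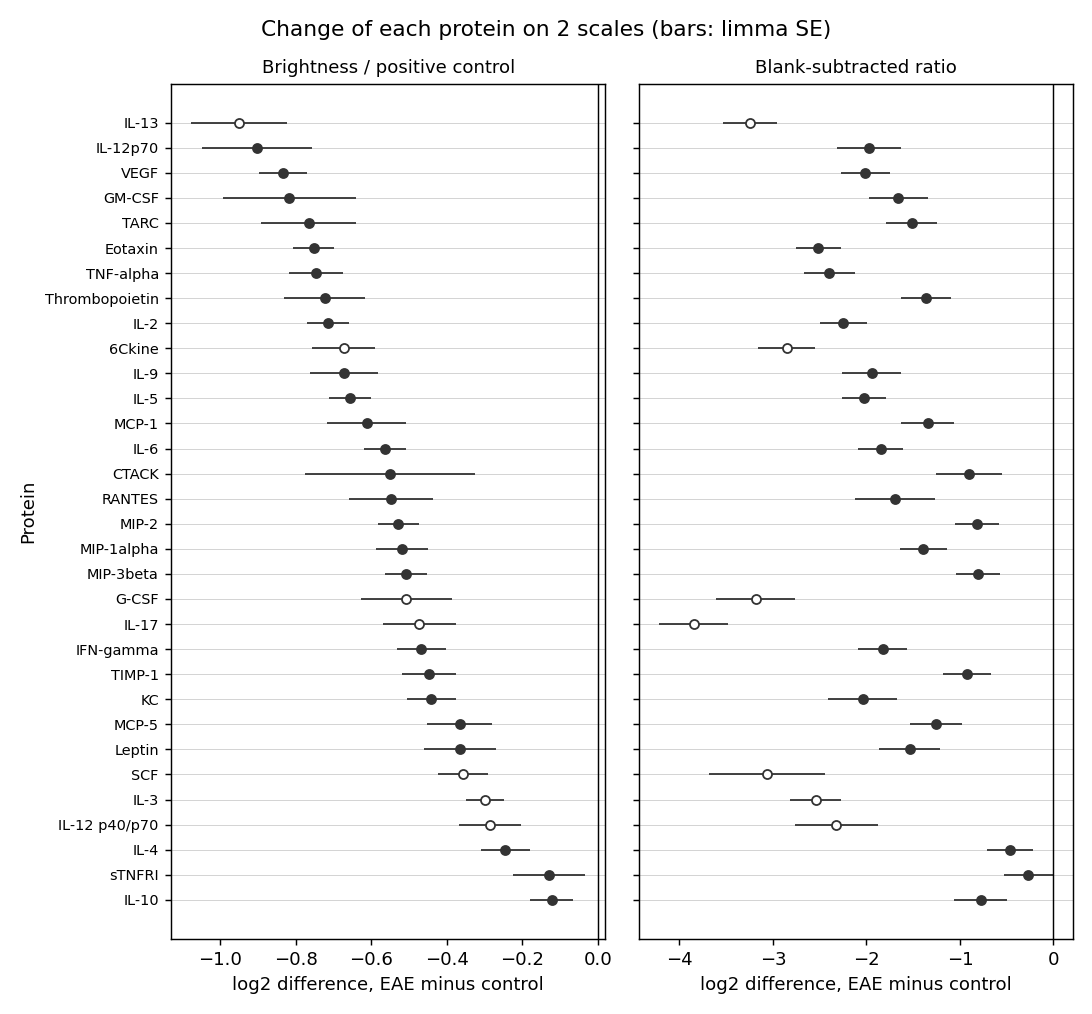
Log2 difference of EAE minus control for each protein (points) with the limma SE (bars), as brightness over the positive control (left) and as normalised signal (right); open points mark the 7 proteins not above background on both EAE arrays. All 32 points, relative to the positive control, are below 0 on both scales (from -0.95 to -0.12 on the left and from -3.85 to -0.27 on the right). The lowest points, IL-13 on the left and IL-17 on the right, are open points, whose EAE levels are upper limits.

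Because the whole panel shifted, the proteins were also compared after each array was scaled to its own median, which removed a log2 brightness shift of -0.66. Relative to that median 4 proteins passed as higher in EAE, IL-10, IL-4, IL-3 and sTNFRI, and 0 as lower (limma, adjusted p from 0.011 to 0.022), with 10 higher and 1 lower at an unadjusted threshold of 0.05. The median protein difference was -0.54, so this scaling left it at 0.12, which tilts these counts towards higher values. In normalised signal relative to its median 7 were higher. The 3 that came out lower, 6Ckine, IL-13 and IL-17, were not above background on either EAE array, so the sizes of their relative differences are not measured. The bounds of 6Ckine and IL-13, at least 4.86-fold and 7.22-fold lower, exceed the panel median of 2.88-fold with bounds or 3.57-fold as measured. That of IL-17, at least 2.79-fold, leaves its direction relative to the panel open. No test was run at these bounds. IL-4, IL-10 and sTNFRI were among those higher on both scales. IL-3 was not above background on either EAE array, so its value of 0.36 ± 0.07 (SE) in relative brightness is that of a scaled background and not a measured difference. In relative normalised signal it was at -0.54 ± 0.24 (SE, adjusted p = 0.11). Quantile normalization left 1 protein past the threshold, IL-4, which was higher in EAE by 0.31 (limma adjusted p = 0.034). The IL-4 and IL-10 calls rest on the EAE values that are not multiples of 0.5. With both proteins left out, median scaling gave 2 calls, IL-3 and sTNFRI (adjusted p = 0.043 each), of which only sTNFRI was above background in EAE, and quantile normalization gave 0 (limma; 2 higher and 0 lower at an unadjusted threshold of 0.05).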

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

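The settings without IL-4 and IL-10, without the 7 proteins below background and with crossed numbers were chosen after seeing the data. Protein calls held under most settings that keep the positive control as the reference, and ended under those that set the panel equal between arrays. The count of 29 lower proteins was 28 to 30 under unscaled intensities, the authors' normalised signal, the offset, normexp, both priors, the replicate block (30; the crossed block, 30) and without IL-4 and IL-10; filters left 23 of 24 and 23 of 25. Both block fits leave 1 residual degree of freedom per protein, so their counts lean on the spread pooled across proteins. The filter at the mean + 2 SD of the background spots removed no protein and tests nothing. The count was 13 by the 1.5-fold rule in brightness and 30 by the same rule in normalised signal, 4 with arrays scaled to the same median and 1 with quantile normalization (0 of them lower in EAE), 2 and 0 with these scalings when IL-4 and IL-10 were also left out, and 19 to 30 with 1 array left out. Both scalings assume an unchanged panel, which by construction removes a shared shift. The median log2 difference of -0.54 was -0.61 unscaled, -1.84 in normalised signal, -0.50 with the offset, -2.27 with normexp, -0.63 after the filter on mean brightness, 0.12 with median scaling, 0.026 with quantile normalization and -0.57 to -0.51 with 1 array left out.

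List medians (log2 brightness) of the T helper 1 and 17, T helper 2 and regulatory, innate, CC, growth factor and platelet lists were -0.59, -0.66, -0.75, -0.55, -0.58 and -0.55. Camera and the replicate block cannot change these medians, and all 6 calls were lost under both: adjusted p was 0.95 and 0.97 with camera and 0.10 for each under the replicate block, with 1 residual degree of freedom; the crossed block ended the growth factor and platelet calls (adjusted p 0.068 and 0.11). Same-numbered samples deviated with a correlation of -0.16 in brightness and 0.33 in normalised signal, so nothing shows that the numbers pair the samples. In the same order the medians were 0.069, 0.0075, -0.084, 0.11, 0.081 and 0.12 with median scaling (adjusted p 0.16 to 0.64) and -0.084, 0.029, -0.11, 0.054, -0.093 and 0.062 with quantile normalization (adjusted p 0.12 to 0.89). With 1 array left out they ranged from -0.67 to -0.58, -0.69 to -0.59, -0.81 to -0.58, -0.73 to -0.51, -0.67 to -0.49 and -0.68 to -0.41.

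Of the 31 named proteins 20 turned to a higher value with median scaling: G-CSF 0.15, IL-3 0.36, IL-4 0.42, IL-5 0.0075, IL-6 0.10, IL-10 0.54, IL-12 p40/p70 0.38, IL-17 0.19, IFN-gamma 0.20, KC 0.22, leptin 0.30, MCP-1 0.050, MCP-5 0.30, MIP-1alpha 0.14, MIP-2 0.13, MIP-3beta 0.15, RANTES 0.12, SCF 0.31, sTNFRI 0.53 and TIMP-1 0.22. Median scaling left the median over all 32 proteins at 0.12, so values of 0.12 or less in this list are not above the typical protein. CTACK, added after its values were seen, also turned, to 0.11, and was -0.14 with quantile normalization. With quantile normalization 17 did: IL-3 0.042, IL-4 0.31, IL-5 0.029, IL-6 0.062, IL-10 0.36, IL-12 p40/p70 0.023, IFN-gamma 0.054, KC 0.062, leptin 0.15, MCP-1 0.054, MCP-5 0.23, MIP-1alpha 0.12, MIP-2 0.043, MIP-3beta 0.065, RANTES 0.062, sTNFRI 0.45 and TIMP-1 0.15. With IL-4 and IL-10 left out, the same 2 scalings also turned sTNFRI, to 0.53 and 0.46, and IL-3, to 0.37 and 0.067. Values of the other named proteins were not compared there. No named protein changed direction under a setting that did not set the panel equal between arrays. Weak signal over background limits the 7 proteins given as bounds.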

Other observations

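The tests in normalised signal relative to its median and those of the 2 patterns were chosen after the data had been seen, whereas median scaling of brightness was chosen before. In normalised signal relative to the median of all 32 proteins, 7 proteins, each above background on all 4 arrays, were relatively higher in EAE past an adjusted p of 0.05 (limma). These were sTNFRI by 1.74 ± 0.28 (log2, SE), IL-4 by 1.54 ± 0.23, IL-10 by 1.23 ± 0.24, the chemokines MIP-3beta, MIP-2 (1.19 ± 0.23) and CTACK (1.10 ± 0.30), and the protease inhibitor TIMP-1 by 1.09 ± 0.24. MIP-3beta, MIP-2, CTACK and TIMP-1 did not pass in brightness relative to its median (limma adjusted p from 0.11 to 0.63). The change in normalised signal rose with control level (Spearman 0.53 over 32 proteins): brighter proteins tended to fall by smaller factors. In brightness the relation ran the other way (-0.52). Both relations take the proteins not above background in EAE at their values as measured, and were not recomputed without them. MIP-2, MIP-3beta and CTACK had the highest control means, at 0.613, 0.563 and 0.535, whereas IL-10 was low at 0.084. On EAE array 2 the IL-10 intensity of 11404.01 lay close above the brightest background value of 11087, so its relative difference depends on the background subtracted. The 2 scales ranked the changes with a correlation of 0.29, or 0.71 over the 24 proteins above background on all 4 arrays. Whether the 7 differ beyond their level was not tested. Eotaxin and TNF-alpha, at -0.51 ± 0.26 and -0.39 ± 0.24 in relative normalised signal, did not pass (adjusted p = 0.15 and 0.23). They passed, at -0.84 ± 0.25 and -0.72 ± 0.25, only among the 24 proteins above background on all 4 arrays, a choice that the fall in EAE itself decides and that moves the reference.

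The first pattern is the fall of all 32 proteins in EAE. Brightness added to every spot of the control arrays is argued against by the negative spots, which fell by 1.33% of the median fall of the proteins. A common factor together with a common amount, as a smaller serum volume with a straight-line response would give, left a residual SD 1.72 times that expected from the replicate spread over all proteins, 1.53 to 2.13 times with any 1 protein left out, lowest without sTNFRI (1.52 times if its replicate spread is kept in the expected SD), and 1.54 times without IL-4 and IL-10. These lie above the limit of 1.5 set after seeing the data, some narrowly. The expected SD rests on 2 samples per group. If their spread is only technical, it is too small to test this account, so the ratios do not exclude it as the whole cause for the panel. Without sTNFRI, IL-4 and IL-10 together it was 1.28 times, but these 3 were picked for their values, so that number decides nothing about the other proteins. Less serum with a response that differs between antibodies stays open, since 0 proteins were higher in EAE and no dilution series was used here, and so does EAE itself, the difference the design names, as no measured protein serves as an independent check of the group labels.

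The second pattern concerns how values were stored. All 64 protein intensities of the control arrays and 60 of the 64 on the EAE arrays are multiples of 0.5, as means of paired whole numbers are. The 4 exceptions are IL-4 (21733.68 and 19756.56) and IL-10 (12483.15 and 11404.01) on both EAE arrays. A mean over more spots is argued against, because 11404.01 needs at least 67 whole readings. Whether these 4 values passed through another step than the rest before deposit, and whether that moved IL-4 and IL-10 up or down, was not tested. Both proteins were among the 3 with the smallest brightness differences in EAE, the other being sTNFRI, whose values are multiples of 0.5. Without IL-4 and IL-10, 28 of 30 proteins were lower in EAE past the threshold.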
